A study of Rattus norvegicus with 13 samples.

How the data were processed

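Expression was measured on 13 GeneChip arrays of rat cortical cultures: 7 of uninjured axons, 3 of regenerating axons and 3 of neurons. Per the labels' protocols, material from 3 microfluidic platforms was pooled for each array, and the RNA was amplified in 2 rounds, the second with biotin. RMA, a method that corrects background, normalises and summarises probe signals, is named in the submitters' processing notes without a version or settings. Scanner files were not used here.

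The deposited value table holds linear ratios, 31099 probe sets by 13 arrays, and not log2 signals as RMA gives them. The deposited ratio of each probe set was examined for its denominator. In every row the median over uninjured arrays 1, 2 and 3 is 1, and likewise over arrays 4, 5 and 6, within a tolerance of 0.0001. In the other 18 sets of 3 of these arrays this holds in at most 60.6% of rows. Array 7 is exactly 1 in every row. The uninjured arrays were therefore treated as 3 ratio sets, in number equal to the 3 culture batches, each divided by its own median. This removes differences between the sets and leaves array 7 without a measurement. Over the regenerating and the neuron arrays the row median is 1 in 0.0933% and 0.0193% of rows, so these were divided by something else, which the sources used here do not give. It was taken to be the uninjured axon level, because the neuron values have a long upper tail (highest ratio 295) and the regenerating values centre near 1 (array medians 1.01 to 1.02). The neuron arrays also have medians near 1 (0.937 to 0.978), so this centring does not single out the reference. Whether the same reference served both groups stays unknown. Across genes, which are not independent replicates, regenerating and neuron arrays correlated at r = -0.33 to -0.17. A ratio carries no signal level, so background and expression cannot be told apart gene by gene. Ratios at the lowest value of the table, 0.01, occur 12 times in regenerating array 2 and 9 times in regenerating array 3. All 13 columns were matched to samples by title.

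Gene symbols came from the array's annotation table and were checked by gene identifier against a table of the GRCr8 assembly, which was used for names only. Of 31042 probe sets that are not controls, 20826 had 1 symbol, 436 had several and 9780 had none. Of the 20826, 20758 had an identifier in the assembly table, and no symbol changed. A gene's value was the mean log2 ratio of its probe sets, giving 14217 genes, of which 4525 had more than 1 probe set. Genes whose probe sets match several symbols, such as beta-actin, GAPDH and many ribosomal proteins, are not among them, and beta-actin and GAPDH were read from control probe sets.

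The tests were planned for log2 signals and were changed to fit ratios. The log2 ratios of the 3 arrays of a group were tested against 0 with limma 3.58.1 (lmFit and eBayes, R 4.3.3). The spread was pooled from those 3 arrays and from the uninjured arrays about the mean of their set, and the reference was given the error of 1 array. Of 27 bacterial control probe sets the group means had an SD of 0.187 (regenerating) and 0.214 (neurons), beside median standard errors of 0.220 and 0.249 over genes. These control probe sets were taken by name to have no spiked transcript, which was not tested. Regenerating axons and neurons were compared with a 2-group limma fit. P-values were adjusted by the method of Benjamini and Hochberg over all genes, with a threshold of 0.05. The planned rule for genes with several probe sets, the probe set with the highest mean, would choose by the outcome when values are ratios, and was run as an alternative.

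Before the data were examined, 30 gene lists were fixed by hand (pathways, neuronal compartments and cell types). They were tested with camera at an inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 30 lists. Array 7 stood for the reference of 1 array in these fits. Fry tests whether a list moves on balance and does not compare it with other genes. Camera called 24 lists for neurons and 14 for regenerating axons, camera with an estimated correlation called none, with 4 and 6 at an unadjusted p under 0.05, and fry called 27 and 5.

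The named genes follow a rule set at the same time. For both main comparisons these are the 6 largest rises and 6 largest falls among genes past the threshold whose groups do not overlap, up to 2 members with the largest rise and 2 with the largest fall of each list among those past the threshold, and 8 fixed genes. Where fewer than 6 genes passed in a direction, those next in order of p were added up to 6. Symbols that begin with LOC or RGD were skipped in the first and last of these. One of the 8 fixed genes, *Actb*, has no probe set with a single symbol. The secondary comparison names the fixed genes only.

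The difference of log2 ratios between 3′ and 5′ control probe sets was compared, as planned for RNA quality. The planned two-sided exact permutation test is not reported, because the uninjured arrays are centred in their sets and an error of the reference is shared by the 3 arrays of a group, so that the arrays are not exchangeable. The fits were tested on simulated ratios for 14217 genes, of which 200 were changed. At 4-fold, 94% of changed genes were recovered for neurons and 92% for regenerating axons, and at 2-fold 31% and 38%. Of 14017 unchanged genes 2 and 5 were called, and 1814 and 1747 when the error of the reference was left out. Of the unchanged genes 14.0% and 14.3% had group arrays apart from the measured uninjured arrays, and the planned 2-group fit called 1671 and 1670 of them.

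Alternatives covered array scaling, array weights, eBayes with a trend, all arrays in 1 fit, a block for the replicate number, other probe set rules, probe sets as units, a 2-fold minimum and leaving out each array. Chosen after seeing the data were the treatments of the reference error, a shift to the bacterial controls and the lowest-numbered probe set. The search for a deviating sample in a group was not applied, since the uninjured arrays form centred sets of 3 in which each of the 30 list medians is exactly 0 in at least 1 array. Applied all the same to the 6 arrays it would mark 17 of the 30 list medians and 32 of 131 named genes. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.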

Results

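Rat cortical neurons were grown for 13 days in a compartmentalised microfluidic platform, a culture device in which axons extend into a chamber apart from the cell bodies and can be harvested by themselves. Polyadenylated RNA was measured on GeneChip arrays in 7 samples of uninjured axons, 3 samples of regenerating axons and 3 samples of neurons from the neuronal compartment. The regenerating axons had been cut on day 11 and had regrown for 2 days. Each array held material pooled from 3 platforms, and the uninjured axons came from 3 culture batches. The deposited value of each of 31099 probe sets is a ratio, and 14217 genes could be named from 20826 of them. Uninjured array 7 reads exactly 1 in every row and holds no measurement, so 6 uninjured arrays carry the spread. The labels do not state what the neuron and regenerating arrays were divided by. It was taken to be the level in uninjured axons, and every direction given here against uninjured axons rests on that reading. The number of arrays limits the precision. The labels do not say that the arrays of a group came from separate cultures, so the spread between samples may be technical. Against uninjured axons, p-values rest on this spread within ratio sets and on an assigned error of the reference. That error was not measured and outweighs that of the 3 arrays, and differences between the sets do not enter. Errors are standard errors of the limma fit (SE, n = 3 arrays) unless stated, and include this assigned error against uninjured axons. They do not cover differences between the probe sets of a gene.

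The comparison of neurons with uninjured axons asks which messenger RNAs are relatively higher in axons and which in the neuronal compartment. A ratio does not show whether a transcript is present in axons. Most measured genes for glycolysis, the proteasome, the secretory pathway and the cytoskeleton were higher in neurons than in axons. Of 14217 genes, 5249 were higher in neurons and 3271 were higher in uninjured axons, and at least 2-fold differences were found in 4264 and 1304 of these. Of the 3271, 110 (3.36%) differed by more than any gene for a smell, taste or pheromone receptor. This class was taken to be largely silent in cortical cells, which was not tested. Of its 41 genes, 32 passed as higher in axons (median log2 -0.98, largest -1.61). The largest of 41 values is no upper bound for background, so the 110 genes are not thereby shown to exceed it. The largest excess in neurons was that of *Nptn*, which encodes the adhesion molecule neuroplastin, at 151-fold (log2 7.24 ± 0.60, adjusted p = 1.73e-05). *Sparcl1*, a secreted matrix protein made mainly by astrocytes, was 94.0-fold higher (log2 6.55 ± 0.39, adjusted p = 4.96e-06). *Serinc1* (log2 6.44 ± 0.61), *Mmadhc*, which acts in vitamin B12 metabolism (6.14 ± 1.04), the deubiquitinase gene *Usp33* (6.12 ± 0.58) and *Zcchc18* (6.11 ± 0.29) followed, with adjusted p-values between 3.11e-06 and 0.000995. The control probe set for the 3′ end of beta-actin read 71.2, 38.4 and 80.1 times the reference in the 3 neuron arrays. The hybridisation controls, transcripts added in a fixed amount, read 0.276, 0.910 and 0.157 times the reference in the same arrays. Less labelled RNA on the axon arrays may therefore contribute to the excess in neurons, which was not tested. Array 2, near the reference in these controls, still read 38.4 for beta-actin.

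Genes for glycolysis, protein turnover, secretion and cholesterol synthesis were higher in neurons almost throughout. All 14 measured glycolysis genes passed in that direction, with a list median of log2 3.43, among them *Gpi* (5.42 ± 0.45) and *Eno1* (4.80 ± 0.26). So did 32 of 34 proteasome and ubiquitin genes (median 3.14), led by *Uchl1* (5.29 ± 0.47), which encodes an abundant neuronal ubiquitin hydrolase, and *Psma3* (5.19 ± 0.37). Of 26 chaperone genes 22 were higher (median 2.91), with *Hspa5* at 5.62 ± 0.79 and *Hsp90ab1* at 5.48 ± 0.54, and of 44 genes of the endoplasmic reticulum and secretory pathway 40 were higher (median 2.43), *Pdia6* by 5.06 ± 0.49. Cholesterol synthesis genes were higher in 18 of 19 cases (median 2.79), *Idi1* by 5.09 ± 0.58 and *Dhcr7* by 4.99 ± 0.53. Camera placed each of these 5 lists above the other genes with a preset correlation, with adjusted p-values from 2.19e-08 to 1.32e-05, and for each of them the adjusted p = 0.263 with an estimated correlation. Translation factors were higher in 28 of 35 cases (median 2.08; adjusted p = 1.32e-05, and adjusted p = 0.328 with an estimated correlation), with *Eif1ax* at 4.49 ± 0.58 and *Eif4a1* at 4.18 ± 0.47.

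A smaller share of the genes for ribosomal proteins and the respiratory chain passed. Of 42 measured cytosolic ribosomal protein genes, 31 did not pass, 10 were higher in axons and 1, *Rpl3* (log2 1.62 ± 0.59), was higher in neurons. Adjusted over the list alone these counts were 7 and 0. The probe sets of *Rpl3* read 0.77 and 2.48. The list median was log2 -0.61, with array medians of -0.26, -1.49 and -0.14. *Rpl21* was 4.91-fold higher in axons (log2 -2.29 ± 0.45, adjusted p = 0.00212) and *Rps28* was 4.09-fold higher (log2 -2.03 ± 0.56, adjusted p = 0.0112). Camera placed the list below the other genes (adjusted p = 0.00247, and adjusted p = 0.595 with an estimated correlation), and fry in limma did not call it (adjusted p = 0.279). Probe sets for ribosomal proteins can read pseudogene transcripts as well, and 42 of 79 listed genes had a probe set with a single symbol. Of 69 respiratory chain genes, 30 were higher in neurons and 1, *Atp5f1e*, was higher in axons (log2 -1.17 ± 0.43). Adjusted over the list alone these counts were 26 and 0. Their median of log2 1.28 came with camera adjusted p = 0.0112, and adjusted p = 0.738 with an estimated correlation. *Atp5pb* (4.68 ± 0.70) and *Ndufs3* (4.56 ± 0.51) showed the largest excess in neurons.

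Cytoskeletal and transport genes were mostly higher in neurons. This held for 36 of 43 microtubule and neurofilament genes (median log2 2.69), including *Dpysl2* (4.60 ± 0.34) and *Crmp1* (4.54 ± 0.33), both collapsin response mediators. It held for 34 of 42 actin cytoskeleton genes (median 2.05), with *Rac1* at 5.81 ± 0.48 and the drebrin gene *Dbn1* at 5.46 ± 0.29, while *Limk1* was higher in axons (-0.94 ± 0.35). Among 34 motor genes 23 were higher in neurons (median 2.00), led by *Dync1h1* (5.05 ± 0.30) and *Dctn1* (5.01 ± 0.26) of the dynein and dynactin complexes. *Mapk8ip3* (-0.62 ± 0.18) and *Kif1b* (-0.59 ± 0.23) were higher in axons. Messenger RNA transport and binding proteins (31 of 39, median 2.00; *Hnrnpab* 4.95 ± 0.60, *Hnrnpd* 4.31 ± 0.31) and nuclear splicing genes (31 of 41, median 1.94; *Ddx39b* 5.60 ± 0.49, *Ddx5* 5.24 ± 0.85) were higher in neurons, with 2 genes of each list higher in axons. These were *Igf2bp2* (-1.24 ± 0.21) and *Igf2bp1* (-1.13 ± 0.29), and *Srsf3* (-1.63 ± 0.52) and *Sf3a2* (-0.77 ± 0.26). Of the axon-side values in this group *Srsf3* alone lies outside the range of the smell, taste and pheromone receptor genes. Of 33 transcripts that earlier work had reported in axons, 28 were higher in neurons and 2, *Oprk1* (-1.23 ± 0.20) and *Creb1* (-0.53 ± 0.20), were higher in axons. The probe sets of *Creb1* disagree in sign, and by its probe set with the highest mean the log2 difference is 0.11 (adjusted p = 0.733). Camera adjusted p-values for these 6 lists lay between 2.19e-08 and 0.000169, and each had adjusted p = 0.263 with an estimated correlation.

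Synaptic and surface proteins differed by gene, and all axon-side values named for them, for regeneration-associated and for immediate early genes lie within the range of the smell, taste and pheromone receptor genes. Presynaptic genes were higher in neurons in 30 of 48 cases and higher in axons in 5, with *Snap25* (log2 4.89 ± 0.61) and *Syngr3* (3.84 ± 0.36) at one end and *Syngr1* (-1.14 ± 0.17) and *Doc2b* (-1.09 ± 0.21) at the other (camera adjusted p = 0.00117, and adjusted p = 0.318 with an estimated correlation). Of 43 postsynaptic and dendritic genes 18 were higher in neurons, among them the receptor subunits *Gria2* (5.04 ± 0.60) and *Gabra5* (3.61 ± 0.52), and 2 were higher in axons, *Synpo* (-0.66 ± 0.20) and *Arc* (-0.46 ± 0.17). Of 65 guidance and adhesion genes 32 were higher in neurons (*Efnb3* 3.68 ± 0.26, *Nrcam* 3.35 ± 0.23) and 4 in axons (*Epha6* -1.04 ± 0.20, *Ephb3* -0.81 ± 0.20). Both lists lay above the other genes (adjusted p = 0.0452 and 0.0151), and both had adjusted p = 0.401 with an estimated correlation. Voltage-gated channels were split 11 to 3 among 33 genes, with *Scn2a* at 3.66 ± 0.33, *Cacna2d1* at 3.51 ± 0.28, *Kcnq3* at -1.46 ± 0.21 and *Scn4b* at -1.20 ± 0.19. Regeneration-associated genes were split 18 to 11 among 43 (*Stmn2* 4.23 ± 0.87, *Scg2* 16.0-fold higher, *Fgf2* -1.37 ± 0.27, *Sprr1a* -1.16 ± 0.18). The probe sets of *Stmn2* differ widely, at 2.53 and 5.93. Immediate early genes were split 9 to 5 among 25 (*Egr1* 9.94-fold higher, adjusted p = 0.0171 in limma, *Jun* 2.34 ± 0.18, *Klf4* -1.13 ± 0.35, *Fosl2* -0.85 ± 0.22). Camera called none of these 3 lists, with adjusted p-values of 0.241, 0.981 and 0.95 in that order (limma, adjusted over the 30 lists).

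Markers of astrocytes and of neurons were mostly higher in neurons, and the axon-side values of cell type markers, except that of *Mki67*, lie within the range of the smell, taste and pheromone receptor genes. Astrocyte genes were higher in neurons in 19 of 25 cases (median log2 1.95), with *Fabp7* at 5.95 ± 1.37 and *Gfap*, the glial intermediate filament gene, at 3.84 ± 0.24. With glial markers higher in the neuron samples, an excess over axons need not come from neuronal cell bodies. Excitatory neuron markers were higher in 14 of 21 cases (*Mef2c* 3.45 ± 0.61, *Lmo3* 2.95 ± 0.37) and higher in axons in 2 (*Rorb* -0.86 ± 0.23, *Tbr1* -0.75 ± 0.27). The probe sets of *Mef2c* differ widely, at 1.47 and 5.42. Transcription and chromatin factors of cortical neurons were higher in 28 of 46 cases, with *Lhx2* at 4.48 ± 0.67 and *Hdac2* at 4.43 ± 0.56, and higher in axons in 3, among them *Eomes* (-1.03 ± 0.36). Camera adjusted p-values for these 3 lists were 1.08e-05, 0.0247 and 0.000526, and with an estimated correlation the adjusted p = 0.263, 0.267 and 0.263. Interneuron markers were higher in neurons in 10 of 18 cases (*Sst* 5.32 ± 0.63, *Calb1* 4.41 ± 0.18) and *Gad2* was higher in axons (-0.82 ± 0.19). Oligodendrocyte genes were split 7 to 4 among 19, with *Olig1* (4.34 ± 0.85) and *Bcas1* (3.44 ± 0.74) against *Opalin* (-1.52 ± 0.27) and *Mog* (-1.38 ± 0.26). Genes of dividing cells were split 6 to 5 among 31, with *Mcm6* (2.77 ± 0.47) and *Mcm7* (2.01 ± 0.73) against *Mki67* (-1.65 ± 0.29) and *Kif23* (-1.30 ± 0.29). Camera gave these 3 lists adjusted p-values of 0.188, 0.95 and 0.772.

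Among the genes that were higher in axons, the 6 largest differences were those of *Rpl37-ps2*, a ribosomal protein pseudogene (11.1-fold, log2 -3.47 ± 0.46, adjusted p = 0.000234), the protease gene *Prss35* (11.0-fold, log2 -3.46 ± 0.50), *Mfap3l* (9.57-fold, log2 -3.26 ± 0.43), the zinc finger gene *Bnc2* (7.73-fold, log2 -2.95 ± 0.56), the muscle myosin gene *Myh1* (6.94-fold, log2 -2.79 ± 0.44) and *Crxos1* (6.26-fold, log2 -2.65 ± 0.50). Lists of cells that are rare in such cultures lay on the axonal side too. Microglia and macrophage markers were higher in axons in 20 of 23 cases and in neurons in none (median log2 -0.94; *Cd74* -1.43 ± 0.20, *Cx3cr1* -1.31 ± 0.27). Inflammatory cytokines and chemokines were higher in axons in 22 of 36 cases (*Ccl5* -1.43 ± 0.24, *Cxcl1* -1.32 ± 0.36) and in neurons in 5 (*Vcam1* 3.21 ± 0.36, *Cx3cl1* 2.61 ± 0.33). Blood markers were higher in axons in 7 of 9 cases (*Hbg1* -1.53 ± 0.31, *Hbb* -1.35 ± 0.18). Fibroblast and vascular markers were higher in axons in 12 of 31 cases (*Col6a1* -1.18 ± 0.24, *Igf2* -0.90 ± 0.21) and in neurons in 3 (*Igfbp2* 2.25 ± 0.42, *Col4a1* 0.92 ± 0.32). Camera adjusted p-values for these 4 lists were 2.46e-07, 9.11e-05, 0.000526 and 0.0145, and each had adjusted p = 0.263 with an estimated correlation. The named axon-side members of these 4 lists also lie within the range of the receptor genes. The 110 genes beyond it included 5 ribosomal protein genes and, by construction, the 6 genes with the largest differences.

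The classical neuronal genes among the fixed genes were higher in neurons or did not pass. The microtubule-associated genes *Mapt* (22.6-fold, adjusted p = 4.61e-06) and *Map2* (3.13 ± 0.51) were higher in neurons, the latter through 1 of its 2 probe sets, which read 6.25 and 0.01. *Gap43*, a growth cone protein gene (1.18 ± 0.39, adjusted p = 0.0260), and the tubulin gene *Tubb3* (1.12 ± 0.25, adjusted p = 0.00377) passed as higher in neurons, but their 2 probe sets disagree, at 2.48 and -0.11 for *Gap43* and at 3.48 and -1.25 for *Tubb3*. *Camk2a* was at 0.39 ± 0.21 (adjusted p = 0.125) and *Bdnf* at 0.49 ± 0.29 (adjusted p = 0.166), and neither passed. The probe sets of both disagree in sign.

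The test was limma on log2 ratios of the 3 neuron arrays, with the reference counted as 1 array and Benjamini-Hochberg adjustment over 14217 genes. In 72.1% of genes the 3 neuron arrays did not overlap the 6 measured uninjured arrays, against 2.38% by chance for exchangeable arrays and 14.0% of unchanged genes in simulated ratios with a shared reference error. The median gene lay at log2 0.22, and once each array was shifted to the same median 4621 genes were higher in neurons and 4269 higher in axons, while the medians of the regeneration-associated, immediate early and oligodendrocyte lists, at 0.20, 0.20 and 0.15, fell on the other side of the median gene.

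**Figure D1:**
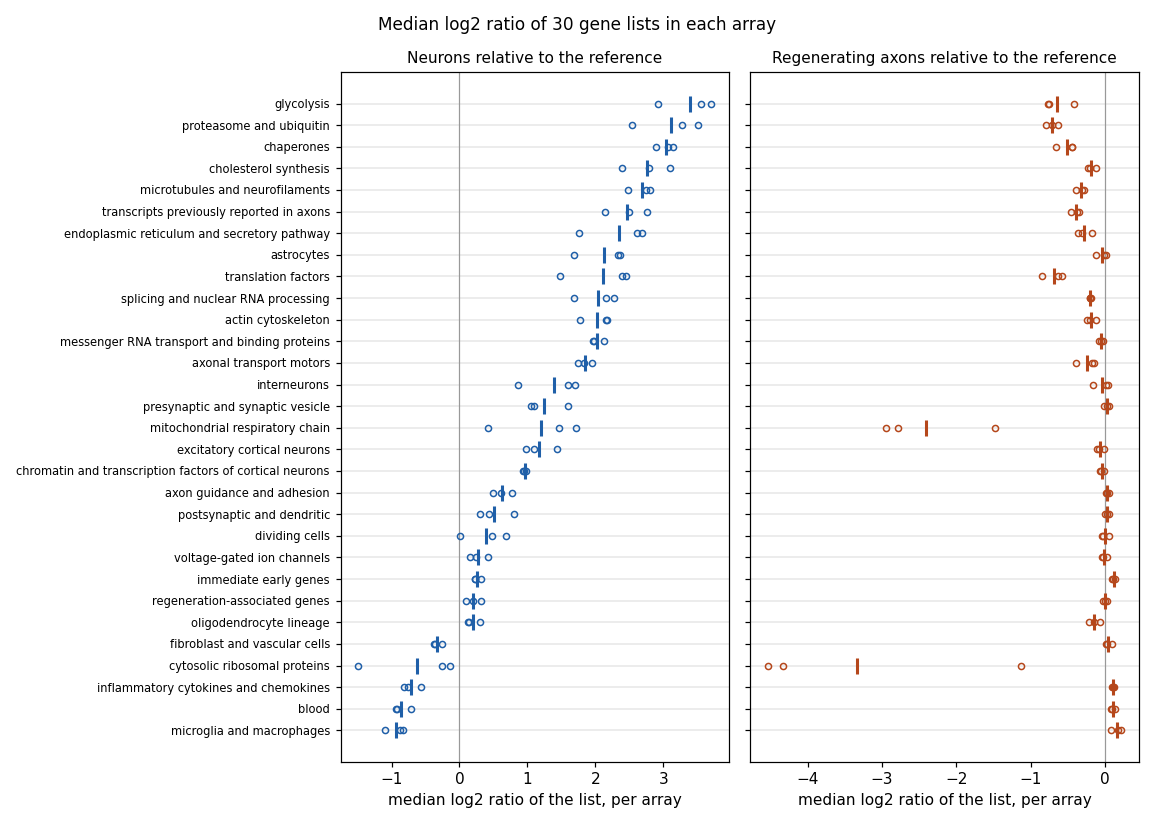
Median log2 ratio to the reference of each of 30 gene lists (rows) in each array, with open circles for the 3 neuron arrays on the left and the 3 regenerating arrays on the right and a vertical tick for the mean of the 3 arrays. Glycolysis, proteasome and chaperone lists are highest in neurons, and cytosolic ribosomal proteins (array medians -1.13, -4.53 and -4.34) and the respiratory chain (-1.48, -2.79 and -2.95) are far below 0 in regenerating axons.

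The comparison of regenerating with uninjured axons asks how the axonal messenger RNA population differs 2 days after axotomy. Of 14217 genes, 98 were lower and 5 were higher in regenerating axons, and 97 and 4 of these differed at least 2-fold. At any p, 749 genes were at least 2-fold lower and 12 at least 2-fold higher. With the error of the reference left out, 1990 genes were lower and 1588 higher. That setting called 1747 of 14017 unchanged genes in simulated ratios, which were drawn with a reference of 1 array. Whether the real reference has that error is not known. The largest fall was that of *Nrep*, a gene known from regenerating neurons, which was 29.2-fold lower (log2 -4.87 ± 0.65, adjusted p = 0.0306). The prefoldin subunit gene *Pfdn5* was 16.3-fold lower (log2 -4.03 ± 0.51, adjusted p = 0.0306), the neuronal catenin gene *Ctnna2* lower as well (log2 -3.59 ± 0.66, adjusted p = 0.0475), and the mitochondrial chaperonin gene *Hspe1* 11.5-fold lower (log2 -3.52 ± 0.55, adjusted p = 0.0342). *Cct7*, a subunit of the cytosolic chaperonin, fell 10.4-fold (log2 -3.38 ± 0.50) and *Cox7b*, a subunit of cytochrome c oxidase, 10.1-fold (log2 -3.33 ± 0.56). The 5 higher genes were the nucleoside transporter gene *Slc28a1* (2.56-fold, log2 1.35 ± 0.20, adjusted p = 0.0306), *LOC100912188* (log2 1.16 ± 0.19), *Wrap53* (2.07-fold, log2 1.05 ± 0.18), the pyruvate dehydrogenase phosphatase gene *Pdp1* (2.01-fold, adjusted p = 0.0459) and the mitochondrial methyltransferase gene *Nsun4* (1.71-fold, log2 0.77 ± 0.14). *LOC100912188* is outside the rule for named genes and was added after its value was seen. Next in order of p were *Plod2* (log2 1.08 ± 0.21, adjusted p = 0.0573) and *Ralgdsl2* (0.86 ± 0.17, adjusted p = 0.0575), which did not pass.

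**Figure D2:**
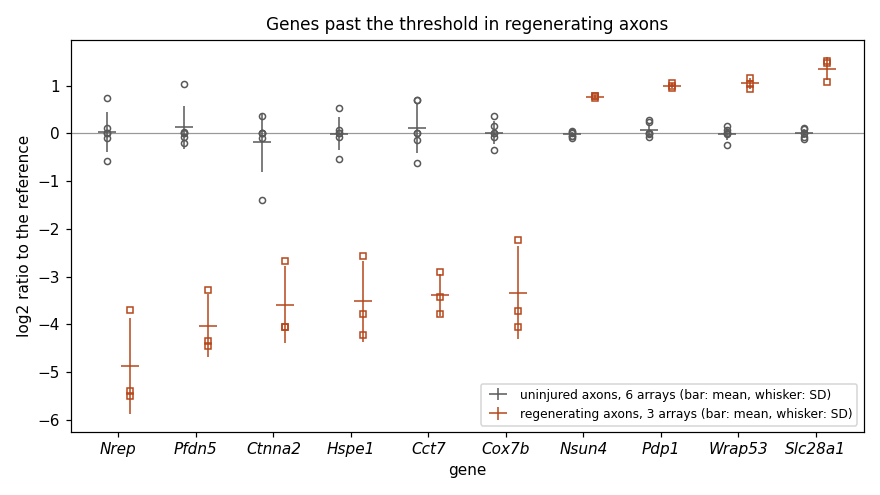
Log2 ratio to the reference of the 10 named genes past the threshold with the largest changes (horizontal axis) in 6 uninjured arrays (circles) and 3 regenerating arrays (squares), with bars for means and whiskers for SD. The genes were chosen among those whose 3 regenerating arrays lie apart from the 6 uninjured arrays. For *Nrep* the mean is -4.87.

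The lowest gene groups in regenerating axons were those for ribosomes and respiration. Respiratory chain genes had a median of log2 -2.50, 5.67-fold lower, and 68 of 69 lay below 0. Of these, 11 passed over all genes and 59 passed adjusted over the list alone, with *Ndufa6* at -2.91 ± 0.42 (adjusted p = 0.0306) beside *Cox7b*. Camera gave the list adjusted p = 2.52e-42, and adjusted p = 0.189 with an estimated correlation. Cytosolic ribosomal protein genes had a median of log2 -3.42, 10.7-fold lower, and 41 of 42 lay below 0, but the 3 arrays differed widely, with medians of -1.13, -4.53 and -4.34. None of the 42 passed in limma over all genes, 39 had an unadjusted p under 0.05, 39 passed adjusted over the list alone, and 39 passed in the 2-group fit that was planned. Camera gave adjusted p = 2.78e-22, and adjusted p = 0.272 with an estimated correlation. The control probe set for the 3′ end of GAPDH, a glycolysis gene, read 2.82, 6.30 and 7.06 times below the reference in the same arrays. The fall was smaller at its 5′ end, which read 0.50, 0.35 and 0.25 times the reference. It was smaller still at the 3′ end of beta-actin, at 0.809, 0.693 and 0.625 times the reference in these arrays. The hybridisation controls, added in a fixed amount, read 1.14, 1.44 and 1.57 times the reference in them, against 0.928 to 1.10 in the measured uninjured arrays. The 3′ minus 5′ difference of control transcripts was also closest to the reference in array 1, at 0.02, -0.63 and -0.40 for beta-actin and -0.48, -1.14 and -0.82 for GAPDH.

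The medians of the other lists lay closer to 0. Camera placed proteasome (1 of 34 lower, median log2 -0.73; *Psma4* -1.90 ± 0.32), translation factor (2 of 35 lower, median -0.63; *Eif3i* -2.29 ± 0.42 and *Eef2* -1.24 ± 0.17), glycolysis (0 of 14 lower and 6 at an unadjusted p under 0.05 in limma, median -0.62) and chaperone genes (3 of 26 lower, median -0.44) below the other genes, with adjusted p-values of 1.59e-08, 7.20e-07, 1.39e-05 and 9.08e-06. With an estimated correlation these became adjusted p = 0.272, 0.284, 0.189 and 0.221. The elongation factor gene *Eef2* has 2 probe sets, at -2.52 and 0.04. Those of the actin gene *Cfl2*, named next, read -2.61 and -0.53. Microtubule genes (2 of 43 lower, 15 adjusted over the list alone; *Tbcb* -1.84 ± 0.34 and *Crmp1* -1.45 ± 0.26), actin genes (1 of 42 lower; the cofilin gene *Cfl2* -1.57 ± 0.27), transcripts that earlier work had reported in axons (1 of 33 lower, *Eef2*) and secretory pathway genes (1 of 44 lower; *Dad1* -1.93 ± 0.32) had camera adjusted p-values of 1.83e-06, 0.000912, 4.31e-06 and 0.000174, and adjusted p = 0.189, 0.189, 0.177 and 0.284 with an estimated correlation. Motor, splicing and cholesterol synthesis genes lay below the other genes without a single gene passing (adjusted p = 0.00865, 0.00564 and 0.0404), each with adjusted p = 0.430 under an estimated correlation, and microglia markers lay above them (median 0.22, adjusted p = 0.0160, and adjusted p = 0.284 with an estimated correlation).

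The remaining 16 lists were not called by camera. Their medians lay between log2 -0.08 and 0.15, including presynaptic genes (0.05, with *Ppfia3* lower at -2.20 ± 0.39), postsynaptic genes (0.01), voltage-gated channels (0.06), guidance and adhesion genes (0.04), regeneration-associated genes (-0.01), immediate early genes (0.15), inflammatory genes (0.12), astrocytes (0.06), blood (0.12) and interneuron markers (-0.05, with the neuropeptide gene *Cck* lower at -2.14 ± 0.37). In limma no gene passed in 20 of the 30 lists, which hold 611 genes, of which 115 had an unadjusted p under 0.05 and 189 passed in the planned 2-group fit. Of the 7 measured fixed genes of neurons and glia none passed in limma, while 4 had an unadjusted p under 0.05 and 4 passed in the planned 2-group fit. *Map2* was at -2.34 ± 0.49 (adjusted p = 0.0689), *Mapt* at -1.01 ± 0.20 (adjusted p = 0.0573), *Gap43* at -1.45 ± 0.48 (adjusted p = 0.211), *Tubb3* at -0.93 ± 0.26 (adjusted p = 0.143), *Camk2a* at 0.23 ± 0.18 (adjusted p = 0.732), *Gfap* at 0.06 ± 0.23 (adjusted p = 0.958) and *Bdnf* at -0.03 ± 0.19 (adjusted p = 0.980). The probe sets of *Gap43* (-3.10 and 0.20), *Tubb3* (-1.98 and 0.13) and *Bdnf* (-0.12 and 0.05) disagree in sign. Those of *Map2* agree in sign but differ widely, at -4.01 and -0.66.

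The counts for regenerating axons rest on how the reference is counted and on single arrays, and in 22.8% of genes the regenerating arrays did not overlap the measured uninjured arrays, against 2.38% by chance for exchangeable arrays and 14.3% of unchanged genes in simulated ratios. The planned 2-group fit called 1581 higher and 1943 lower genes, with an eBayes trend none passed, and the number of lower genes was 0 without regenerating array 3, 3 without regenerating array 2, 361 without regenerating array 1, 4, 8, 151 and 256 without uninjured arrays 2, 6, 3 and 1, and 66 without uninjured array 5.

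Regenerating axons were also set against neurons, which is a secondary comparison that shares its arrays with the others and assumes 1 reference for both groups. Of 14217 genes, 4444 were higher and 6279 lower in regenerating axons (limma, 3 arrays against 3). *Mapt* was 45.4-fold lower (log2 -5.50 ± 0.18, adjusted p = 5.73e-07), *Map2* 44.1-fold lower (log2 -5.46 ± 0.20), *Gfap* 13.7-fold lower (log2 -3.78 ± 0.17), *Gap43* 6.22-fold lower (log2 -2.64 ± 0.27) and *Tubb3* 4.12-fold lower (log2 -2.04 ± 0.16), while *Bdnf* (log2 -0.52 ± 0.21, adjusted p = 0.0537) and *Camk2a* (-0.17 ± 0.14, adjusted p = 0.311) did not pass. The probe sets disagree in sign here too for *Gap43* (-5.58 and 0.31), *Tubb3* (-5.46 and 1.38), *Bdnf* (-1.16 and 0.12) and *Camk2a* (from -0.96 to 1.04). Those of *Map2* agree in sign but differ widely, at -10.25 and -0.67, so its fold is an average of unlike values. Respiratory chain genes were lower in 68 of 69 cases (median log2 -3.79), glycolysis genes in 14 of 14 (-4.33), proteasome genes in 33 of 34 (-4.21) and ribosomal protein genes in 26 of 42 (-2.59). Microglia markers were higher in 21 of 23 cases (median 1.12). Camera called 24 of the 30 lists, none of which passed with an estimated correlation (adjusted p = 0.299 at the smallest). In 79.8% of genes the groups did not overlap, against 10% by chance if the reference was the same.

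The balance between the ends of control transcripts was compared with that in the reference. Reverse transcription from the tail and repeated amplification favour the 3′ end, and the 3′ minus 5′ difference of log2 ratios shows how far a group departs from its reference in this. For beta-actin it was 0.60 ± 0.18 (SD, n = 3) in neurons and -0.33 ± 0.33 (SD, n = 3) in regenerating axons, against 0.09 ± 0.12 (SD, n = 6) in uninjured axons. For GAPDH it was -2.02 ± 0.25 (SD, n = 3) in neurons and -0.81 ± 0.33 (SD, n = 3) in regenerating axons, against 0.08 ± 0.21 (SD, n = 6) in uninjured axons. In both transcripts all 3 neuron arrays lay on the same side of all measured uninjured arrays, as did the 3 regenerating arrays for GAPDH, and the sign in neurons was opposite for the 2 transcripts. No p-value is given, because an error of the shared reference moves all 3 arrays of a group to the same side.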

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

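The test on hybridisation controls was chosen only after the result was seen, and no biological explanation could be tested on its own. Ribosomal protein and respiratory chain transcripts were lower in all 3 regenerating arrays, with joint medians over 111 genes of log2 -1.33, -3.35 and -3.42. The 3′ minus 5′ difference of GAPDH was likewise smallest in array 1 (-0.48, -1.14 and -0.82), and its part was not tested. In neurons this difference had opposite signs for beta-actin (0.60) and GAPDH (-2.02), so it cannot be read as RNA quality alone. A range of 0.66 over the 6 measured uninjured arrays, which is also the largest difference within a set, leaves differences between axonal samples and a deviating reference open, because differences between the ratio sets were removed, array 7 holds no measurement and the denominator of the regenerating arrays is unknown. Uninjured array 1, with the lowest joint median of these 6 (-0.45), correlated with the regenerating arrays at r = 0.41, 0.53 and 0.53. These correlations run across genes, which are not independent replicates. Array 3 (joint median 0.20) correlated with them at -0.35 to -0.33. Arrays 1 and 3 were divided by the same median and correlated at -0.43, so array 3 is not separate support. By array 1 alone, part of the profile also varied among uninjured samples. Less labelled RNA from the regenerating samples may contribute, since the hybridisation controls were higher in each regenerating array (lowest log2 0.19) than in any measured uninjured array (highest 0.13), though an error of the reference would move all 3 alike. A response to axotomy stays open as untested, and so does transcript length, for which no transcript sequences were used here.

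The tests of absent cell types were written before their results were seen. Of the microglia list 20 of 23 genes and of the blood list 7 of 9 passed as higher in axons than in neurons, and of inflammatory cytokines and chemokines 22 of 36 did, with 5 higher in neurons. The microglia list had a median log2 of -0.94 over 23 genes (bootstrap 95% interval -1.02 to -0.74). It lay 0.0433 from chemosensory receptor genes (bootstrap 95% interval of the difference -0.18 to 0.23). Both intervals resample genes, which are not independent replicates, and do not measure the spread between samples. By these medians, microglia in the axonal compartment are argued against as the source of the excess of the list as a whole. This rests on silent receptor genes, which was not tested, and a small contribution of microglia would not be seen. Background signal of dim axonal arrays is a candidate explanation, because the receptor genes lay at -0.98, as far below the reference in neurons as the microglia list. Other values go the other way, if the 27 bacterial control probe sets had no spiked transcript, which was assumed. They had a median of log2 0.03 in neurons. In neuron array 2 the hybridisation controls read 0.910 times the reference, yet the microglia list had a median of -0.83 there, beside -0.87 in array 1. Dim arrays are therefore not established as the cause. No gene of the list exceeded the receptor genes (*Cd74*, log2 -1.43, came closest). Myeloid genes outside it, chosen after their values were seen, did, among them *Mrc1* (-2.45), *Lilrb2* (-2.29) and *Nrros* (-1.80). So did genes of other tissues (*Myh1* -2.79, *Adipoq* -1.98), and the source of both kinds stays open. Differences of up to -1.61, the largest of a receptor gene, are open to the same reading among the 3271 genes higher in axons. Larger differences are not shown to be free of it, since few receptor genes set this range.

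Uninjured array 4 was higher in transcripts enriched in neurons; the test of neuronal RNA was written after the correlation had been seen. The 200 genes highest in neurons had a median log2 of 0.34 in array 4 against -0.07 to 0 in the other 5 measured uninjured arrays, and its log2 ratios correlated with the neuron means across genes (r = 0.36, rho = 0.29; genes are not independent replicates). This does not single out neuronal cell bodies, since *Fabp7* (3.87), *Olig1* (2.64), *Mcm7* (2.13) and *Bcas1* (2.03) of glia and dividing cells exceeded *Gria2* (1.43) and *Snap25* (1.26), *Mapt* (-0.03) and *Stmn2* (-0.05) stayed near 0, and 24 neuronal and 26 glial markers higher in neurons had medians of 0 and -0.05, while 6 markers of dividing cells had a median of 0.73 (5 above 0). The joint median of 0 of ribosomal protein and respiratory chain genes decides nothing on a general excess of RNA, as the arrays are centred. The source stays open, and no biological explanation was tested.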

How the results depend on the processing

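The treatments of the reference, the bacterial shift and the lowest-numbered probe set were chosen after seeing the data. Against neurons, the counts stayed within 1.5 times under every alternative run except probe sets as units (8820 higher in neurons, 8523 higher in axons, with unnamed probe sets included) and the 2-fold minimum (1304 higher in axons). Leaving out single arrays gave 4770 to 5824 and 2711 to 3500. For regenerating against uninjured axons (5 higher, 98 lower), leaving out single arrays gave 0 to 15 higher and 0 to 361 lower. All 13 arrays in 1 fit gave 2 and 48, probe sets 3 and 104, the bacterial shift 3 and 90. An eBayes trend gave 0 and 0 (1769 genes at an unadjusted p under 0.05 without it), where the trend runs over mean ratios that contain the change itself. The reference counted as 3 arrays gave 300 and 1018, its error left out 1588 and 1990, and the planned 2-group fit 1581 and 1943, since these count a smaller error. Regenerating axons against neurons kept both counts within 1.5 times.

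Whether the replicate numbers pair the samples stays open. Same-numbered deviations correlated at -0.40, -0.07 and -0.16 between uninjured and regenerating arrays. They correlated at -0.17, -0.04 and 0.16 between uninjured arrays and neurons, and at 0.17, 0.18 and -0.11 between regenerating arrays and neurons. Only 0.16 (highest other number 0.13) and 0.18 (highest other number -0.12) exceeded every differently numbered array. Centring within groups constrains these values, so they cannot exclude a pairing. With a replicate block 38 and 319 genes were called for regenerating axons, 5956 and 3984 for neurons, and 4235 and 6189 between them. The call of the ribosomal protein list (median -3.42) was lost with camera at an estimated correlation (adjusted p = 0.272) and fry (0.101), and that of the respiratory chain list (-2.50) with an estimated correlation (adjusted p = 0.189). The block gave medians of -3.28 and -2.28. Without single arrays the medians ran from -4.49 to -2.88 and from -2.92 to -2.21. Against neurons, 3 genes turned sign: *Creb1* (0.11) and *Gap43* (-0.11) by the probe set with the highest mean, *Tubb3* (-1.25) by the lowest-numbered, since their probe sets disagree. Cyclic loess and the filter on dim genes were not run, as ratios carry no level, nor was the fit without uninjured array 7. The mean of all probe sets, planned as an alternative, became the main rule. Signal over background is unknown and limits every call near the reference.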

Other observations

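Mitochondrial ribosomal proteins were grouped after the genes lower in regenerating axons had been seen. Of 73 such genes 6 were lower in regenerating axons (*Mrpl27*, *Mrpl54*, *Mrps21*, *Mrps33*, *Mrps35* and *Mrpl12*), from log2 -3.01 ± 0.43 for *Mrpl27* to -0.91 ± 0.17 for *Mrpl12* (SE, n = 3, limma). The group's median was -0.49, with array medians of -0.46, -0.53 and -0.49, and 59 of 73 lay below 0. In neurons 39 of the 73 were higher and 1 was lower than in uninjured axons, with a median of log2 1.33. Thus the 3 regenerating arrays, which differed by more than 3 log2 units in cytosolic ribosomal proteins, were close to each other in this group. Single genes with low adjusted p in regenerating axons included *Slc49a4* (log2 -2.16 ± 0.21, adjusted p = 0.0159), *Pcbd2* (-2.38 ± 0.24, adjusted p = 0.0159), *Park7*, the Parkinson disease gene DJ-1 (-2.87 ± 0.31, adjusted p = 0.0168), and the granule protein gene *Chga* (-2.36 ± 0.37, adjusted p = 0.0342).

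Chance was examined with the planned 2-group fit, since the ratio test has no second group to exchange. Of 100 splits of the 10 arrays, 1, the real split, gave as many as 11634 genes for neurons, the highest other split giving 3, and 1 of 100, the real split, gave 3524 for regenerating axons, the highest other giving 172. Chance is not excluded by this for either, since the uninjured arrays are centred and the reference error is shared by a group's arrays: in simulated ratios the same fit called 1671 and 1670 of 14017 unchanged genes. For regenerating axons against neurons, 10 splits are too few for a share under 0.05, and the real split gave 10723 genes and the highest other 0, with 1 split reaching the real value.

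The hybridisation controls read 0.276 and 0.157 times the reference in neuron arrays 1 and 3 and 0.910 in neuron array 2. The 18 control probe sets had medians of 0.928 to 1.10 in the measured uninjured arrays. Neuron array 2 also had the lowest median of the 3 neuron arrays in 22 of the 30 gene lists, among them glycolysis (log2 2.92, beside 3.56 and 3.70), the respiratory chain (0.42, beside 1.47 and 1.72) and ribosomal proteins (-1.49, beside -0.26 and -0.14).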
